A study of Mus musculus with 12 samples.

How the data were processed

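Messenger RNA was measured in whole spinal cords of mice whose Ddx20 alleles carry loxP sites and whose Plp-CreER driver acts after tamoxifen, and in control mice. There were 12 libraries in 4 groups of 3 animals: control and cKO at 4 weeks, and control and cKO at 4.5 weeks after tamoxifen. Poly(A) RNA libraries were made with the TruSeq RNA Sample Prep Kit v2, which does not mark strand, so reads of a gene and of an overlapping or antisense partner cannot be told apart.

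The authors deposited one table of estimated counts per gene for each time, not scaled by depth or length, and STAR, RSEM and the mouse build mm39 are named in the submitters' processing notes with no versions or parameters. The gene annotation release is not given there. Of the values, 3.25% to 3.81% per library were not whole numbers. Both tables hold the same 56953 genes in the same order. Columns were assigned to samples by the time in the name of their table and by the genotype and number in the column name. A symbol was missing for 6753 genes, which held 0.337% to 0.519% of the counts and were kept under their identifiers. Spreadsheet dates stood in place of 27 symbols, which were restored from the gene identifiers. Library totals lay between 33104560 and 47677267 counts.

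The estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filter on low counts with the 4 groups, which left 19278 genes. Libraries were scaled by trimmed mean of M values. All 12 libraries entered 1 model with a mean per group, and 5 contrasts were tested with edgeR's quasi-likelihood F test: cKO minus control at 4 weeks, the same at 4.5 weeks, the difference of those effects, their mean, and control at 4.5 weeks minus control at 4 weeks. P-values were adjusted by Benjamini and Hochberg over all genes tested in a contrast, and a gene was called at an adjusted p below 0.05. Unless a sentence says otherwise, each adjusted p for a gene comes from this edgeR test, each log2 fold change is cKO minus control with its standard error (SE), and levels are counts scaled to a common library size (CPM) with the standard deviation (SD) over 3 libraries. Ddx20 was also compared with an exact 2-sided permutation test of CPM, whose smallest possible p with 3 against 3 libraries is 0.1.

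The model, the contrasts, 38 gene lists and the rule for named genes were fixed before the data were examined. Of the lists, 12 were core lists. The rule named Ddx20, the 4 largest rises and the 4 largest falls at each time among called genes with a mean log2 CPM of at least 1 and no overlap of the 3 cKO with the 3 control libraries, leaving out provisional symbols. It added the 2 called members of each core list with the smallest p, the 4 largest differences in each direction between the times, the 2 largest in each direction between the control groups, and at most 2 called members of any other list described. Genes named outside this rule are marked as chosen after their values were seen. Some genes the rule chose are not reported here. Members named as the exceptions of a list are such genes. In each gene named by the rule and called at a time, all 3 libraries labelled cKO lay outside the range of the 3 controls, except Dnajb1 and Cdh19 at 4 weeks and Acta1, Slc22a6 and Ranbp3l at 4.5 weeks (2 of 3 each).

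Lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry, adjusted over the lists of a contrast. Camera compares a list with all other genes, and fry asks whether its members moved, on balance, one way. Some lists share members: Sesn2 and Gdf15 stand in both the p53 target and the integrated stress response list, Bax and Fas in the p53 target and cell death lists, and Rps27l in the p53 target and ribosomal protein lists. Atf3 stands in the integrated stress response and axon injury lists, Hspb1 in the reactive astrocyte and axon injury lists, and Zbp1 in the interferon and cell death lists. Csf1, Ccl3 and Ccl4 stand in the disease-associated microglia and cytokine lists, Tnf and Il1b in the cell death and cytokine lists, and Cxcl10 in the reactive astrocyte, interferon and cytokine lists.

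The results were also computed with size factors of DESeq2 in edgeR, upper quartile scaling, no filter on low counts, a minimum of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, each time fitted alone, a robust spread, a replicate block, a test against a 1.5-fold change, mitochondrial and haemoglobin genes left out, and each library left out in turn. Another 3 were chosen after the data were seen: a sex term, control libraries 1 and 2 of 4.5 weeks left out together, and a trend with transcript length removed from each library. Transcript lengths came from GENCODE M21, used for lengths and symbols only. A planned analysis of genes with minor introns was not run because a genome sequence was not used here. Folds for genes at 1 to 4 counts in a group are ratios of summed counts with a 95% interval of counting error, and where a group held 0 counts a lower bound was computed with a floor of 3 counts per library. Intervals and floors cover counting error only.

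The steps were tested on simulated counts for 18908 genes with known changes, drawn independently for each gene. Far fewer genes were changed than were called in the data (214 calls at 4 weeks and 88 at 4.5 weeks). The shares below therefore need not carry over to the data. At 4 weeks, 6% of changes of 1.25-fold, 46% of 1.5-fold, 69.6% of 2-fold and 78% of 4-fold were recovered, and 2.34% of calls were false. At 4.5 weeks these shares were 8.16%, 34%, 59.2% and 74%, with 1.14% false. The difference between times gave 2.02%, 31%, 54.7% and 72% with 5% false, the mean effect 2.02%, 23%, 52.6% and 76% with 3.17% false, and the control groups 14.3%, 54%, 69.4% and 93.9% with 5.79% false. Camera called 10 of 10 shifted lists and 0 of 10 unshifted lists at 4 weeks. With independent draws this cannot check the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.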

Results

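Spinal cord messenger RNA was compared between control mice and mice with loxP-flanked Ddx20 alleles and the tamoxifen-activated Plp-CreER driver, which acts in oligodendrocyte-lineage cells. The 12 libraries formed 4 groups of 3 animals, control and cKO at 4 and at 4.5 weeks after tamoxifen. They held 33104560 to 47677267 counts and 23282 to 24999 detected genes each, and 19278 genes were tested. Along the first principal component (62.3% of the variance) the 6 controls lay between -60.5 and -76.2, the libraries labelled cKO at 4 weeks at 0.695, 43.3 and 33.4, and those at 4.5 weeks at 110, 108 and 106. Mitochondrially encoded genes held 5.7% to 7.34% of the counts.

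Transcript of the targeted gene, Ddx20, which encodes the helicase Gemin3 of the complex that assembles splicing ribonucleoproteins, was not lower in the libraries labelled cKO. At 4 weeks the controls held 11, 9.78 and 11.1 CPM and the libraries labelled cKO 10.2, 11.1 and 9.9 CPM. The log2 fold change was -0.03 (95% interval -0.254 to 0.191), with an adjusted p of 0.84 from edgeR's quasi-likelihood test and an exact permutation p of 0.9. At 4.5 weeks Ddx20 was higher: the controls held 9.16, 10.6 and 9.71 CPM and the libraries labelled cKO 12.4, 11.1 and 13.3 CPM (log2 fold change 0.33, 95% interval 0.103 to 0.548, adjusted p 0.013, exact permutation p 0.1, the smallest possible). That call was lost without control library 1 (adjusted p 0.06) or without cKO library 3 (adjusted p 0.063) of that time, and over all alternatives its adjusted p ranged from 0.0026 to 1. The difference in Ddx20 effect between the times (0.36, adjusted p 0.068) and the difference between the control groups (-0.11, adjusted p 0.5) were not called. Counts per gene do not resolve a deleted exon, and Plp-CreER acts in only part of the cells of the cord.

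**Figure D1:**
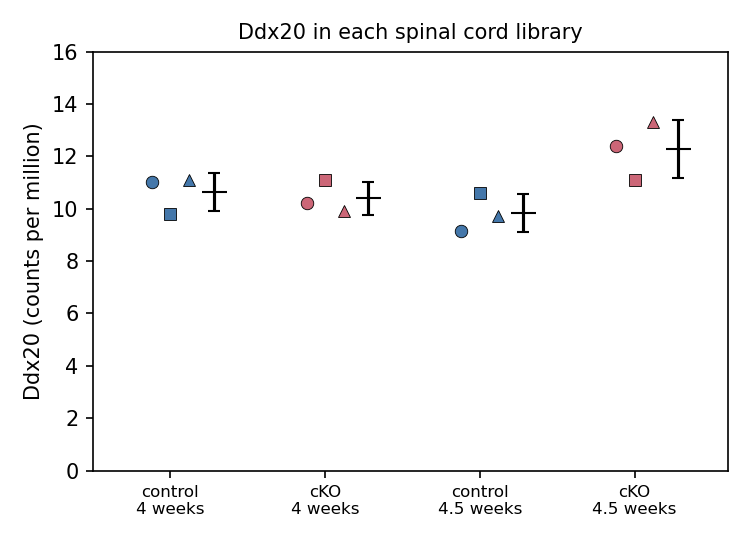
Ddx20 in CPM in each library by genotype and time, with bars showing the mean and SD of 3 libraries. The libraries labelled cKO overlap the controls at 4 weeks and lie above them at 4.5 weeks.

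Sex, read from Xist and Y-linked transcripts, was not balanced. The X-inactivation transcript Xist had 2, 0 and 2 counts in the controls at 4 weeks, 13563, 14773 and 3 in the libraries labelled cKO at 4 weeks, and between 16090 and 30525 in each library at 4.5 weeks. The controls at 4 weeks were thus male, cKO libraries 1 and 2 of 4 weeks female and library 3 male, and all 6 libraries of 4.5 weeks female. A sex term in the model can be estimated only within the libraries labelled cKO at 4 weeks, so the effect at 4 weeks then rests on 1 male cKO library.

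Transcripts of genes listed for neighbouring tissues also varied. Avil, of sensory ganglion neurons, held at most 0.742 CPM in the controls at 4 weeks but 15.5 to 23.5 CPM in the libraries labelled cKO. At 4.5 weeks it held 36.1 CPM in control library 1, 0.259 and 0.627 CPM in the other 2 controls, and 10.1 to 13.1 CPM in the libraries labelled cKO. Scn7a, a sodium channel gene of Schwann and ganglion cells, held 28.1 CPM in the same control library and at most 5.73 CPM in the libraries labelled cKO. Trpv1, of the same list as Avil, held 3.46 CPM in that control library and at most 0.215 CPM in the other controls. In the libraries labelled cKO it held 1.66 to 4.6 CPM. Outside that control library, Avil and Trpv1 thus followed genotype at both times, and the tissue they came from was not tested. Acta1, of skeletal muscle, reached 53.9 CPM in control library 2 of 4.5 weeks.

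At 4 weeks, genes of mature oligodendrocytes were lower in the libraries labelled cKO. Ermn, a cytoskeletal protein of oligodendrocytes, held 88 ± 16 CPM (mean ± SD, n = 3) against 389 ± 14 CPM in controls (log2 fold change -2.15 ± 0.13 SE, adjusted p 2e-07). Aspa, which cleaves N-acetylaspartate in oligodendrocytes, held 13.6 ± 2.7 against 58.5 ± 1.3 CPM (-2.11 ± 0.12, adjusted p 7.9e-08). Of 28 myelin and mature oligodendrocyte genes, 27 were lower and 0 higher (also 27 adjusted over the list alone), with a median log2 fold change of -1.16. Camera called the list (adjusted p 2.9e-42). Mbp, of the myelin sheath and chosen after its values were seen, fell by -0.83, and the only member not called was Nkx6-2 (-0.11, adjusted p 0.28).

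Sterol genes were lower as well at 4 weeks. Hmgcs1, an early enzyme of the mevalonate pathway, held 244 ± 5.4 CPM in the libraries labelled cKO against 543 ± 14 CPM (log2 fold change -1.16 ± 0.067, adjusted p 1.2e-07), and Sqle, which makes squalene epoxide, held 64.8 ± 2 against 122 ± 0.31 CPM (-0.91 ± 0.054, adjusted p 1.5e-07). Of 21 cholesterol synthesis genes 20 were lower (21 over the list alone), with a median of -0.774 and a camera adjusted p of 2.6e-25. Ebp was the member not called.

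Earlier stages of the lineage moved less at 4 weeks. Matn4, a matrix protein of progenitors, rose from 9.33 ± 0.59 to 34.3 ± 8.9 CPM (log2 fold change 1.88 ± 0.15, adjusted p 2.1e-06), and Cspg4, the NG2 proteoglycan, from 22.7 ± 1.6 to 50.7 ± 5.9 CPM (1.16 ± 0.1, adjusted p 4.7e-06). Of 14 oligodendrocyte progenitor genes 4 were higher (Cspg4, Matn4, Vcan and Emid1) and 1, C1ql1, was lower, the same counts as over the list alone, and camera did not call the list (median 0.0289, below 0 without cKO library 2 of 4 weeks, adjusted p 0.16). Of 14 genes of newly formed oligodendrocytes 2 were higher and 3 lower (same over the list alone), and the list was not called (adjusted p 0.46). Its median of -0.119 and mean of 0.0237 differed in sign. Among these, Rras2, a small GTPase, was higher (0.75 ± 0.2, adjusted p 0.011) and Enpp6, a choline phosphodiesterase, lower (-0.53 ± 0.17, adjusted p 0.024). With a sex term neither was called (Rras2 0.555, adjusted p 0.17, range over all alternatives 0.0014 to 0.52; Enpp6 -0.684, adjusted p 0.065, range 0.0035 to 1). Enpp6 was also lost without control library 2 (adjusted p 0.068) or 3 (0.051) or cKO library 2 (0.094) or 3 (0.09) of 4 weeks. The list held 3 calls without control library 1 or 2, and 1 without control library 3 or cKO library 2 or 3 of 4 weeks.

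Targets of p53 rose at 4 weeks as a whole list. Gtse1, which binds p53 and is made in late cell cycle, rose from 1.02 ± 0.22 to 41.5 ± 2.6 CPM (log2 fold change 5.33 ± 0.14, adjusted p 6.1e-10), and Eda2r, a receptor of the TNF family, from 0.812 ± 0.21 to 32 ± 1.7 CPM (5.29 ± 0.16, adjusted p 9.5e-10). All 25 p53 targets were higher (25 over the list alone), with a median of 2.57 and a camera adjusted p of 4.8e-117. Gdf15, a stress hormone that is also counted in the integrated stress response, rose from 0.167 ± 0.039 to 148 ± 47 CPM (9.75 ± 0.36, adjusted p 2.8e-09), and Sesn2, a sestrin shared by the same lists, from 19.5 ± 1.4 to 79.5 ± 6 CPM (2.03 ± 0.076, adjusted p 3.1e-09).

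The integrated stress response list, which includes Gdf15 and Sesn2, was divided at 4 weeks. Of 20 genes 8 were higher and 3 lower (9 and 3 over the list alone), with a median of 0.263 (0.42 without control library 3 of 4 weeks) and a camera adjusted p of 1.1e-04. The 3 lower genes were Psat1 (-1.11) and Phgdh (-0.73), of serine synthesis, and Vldlr (-0.33), a lipoprotein receptor.

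Cell death genes rose with p53 targets at 4 weeks. Bax, which permeabilises mitochondria, rose from 27.5 ± 1.6 to 84.5 ± 3.4 CPM (log2 fold change 1.62 ± 0.065, adjusted p 6.4e-09), and the death receptor Fas from 3.38 ± 0.58 to 23.8 ± 2.9 CPM (2.81 ± 0.15, adjusted p 5.5e-08). Both also stand in the p53 list. Of 25 cell death genes 22 were higher and 1, Il18, lower (23 and 1 over the list alone), with a median of 1.59 and a camera adjusted p of 3.4e-17 (adjusted p = 0.1 with an estimated correlation).

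Some SMN complex and spliceosomal genes were modestly higher at 4 weeks. Snrpa1, a protein of the U2 particle, rose from 24.7 ± 1.7 to 40.7 ± 3.2 CPM (log2 fold change 0.72 ± 0.074, adjusted p 1.4e-05), and Snrpc, of the U1 particle, from 20.7 ± 1.6 to 33.6 ± 2.4 CPM (0.70 ± 0.085, adjusted p 4.8e-05). Neither passed a test against a 1.5-fold change (adjusted p 0.12 and 0.26, the highest over all alternatives, the lowest being 9.6e-16 and 9e-12 with DESeq2). Of 26 SMN complex and spliceosomal genes 12 were higher, 1, Wdr77, lower and 13 not called (same over the list alone, 0 called against a 1.5-fold change), with a median of 0.271 and a camera adjusted p of 0.0063 (adjusted p = 0.37 with an estimated correlation).

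Ribosomal protein genes shifted together at 4 weeks. Rps19, of the small subunit, rose from 134 ± 13 to 283 ± 17 CPM (log2 fold change 1.08 ± 0.072, adjusted p 3.8e-07), and Rps27l, also a p53 target, from 14.3 ± 0.21 to 58.7 ± 8.1 CPM (2.03 ± 0.1, adjusted p 3.7e-08). Of 80 genes 76 were higher and 0 lower (77 over the list alone), with a median of 0.443 and a camera adjusted p of 2.6e-25 (adjusted p = 0.24 with an estimated correlation). Reads of these genes are uncertain where processed pseudogenes share their sequence.

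Microglial genes were higher at 4 weeks. Trem2, a lipid receptor of microglia, rose from 12.1 ± 0.48 to 59.7 ± 11 CPM (log2 fold change 2.31 ± 0.1, adjusted p 1.5e-08), and Ctsd, a lysosomal protease, from 531 ± 10 to 2150 ± 240 CPM (2.02 ± 0.096, adjusted p 2.3e-08). Of 24 disease-associated microglia genes 22 were higher (22 over the list alone), with a median of 2.36 and a camera adjusted p of 5.7e-40. Fabp5 and Igf1 were not called. Fcrls, an Fc receptor-like gene of resident microglia, rose from 13.6 ± 0.64 to 97.6 ± 23 CPM (2.84 ± 0.15, adjusted p 6.3e-08). Of 13 homeostatic microglia genes 10 were higher and 1, the transcription factor Sall1, lower (same over the list alone). The median was 0.837 and the camera adjusted p 1.8e-08 (adjusted p = 0.095 with an estimated correlation).

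Complement, cytokine, antigen presentation and proliferation genes rose alongside at 4 weeks, in each list least in cKO library 1. Its mean log2 CPM of cytokine genes was 0.842, against 3.364 and 2.587 in cKO libraries 2 and 3. For proliferation genes it was 1.595 against 3.212 and 2.844. C3ar1, the C3a receptor, rose from 2.15 ± 0.27 to 23 ± 7.9 CPM (log2 fold change 3.42, adjusted p 3.9e-07), the chemokine Ccl3 from 0.336 ± 0.097 to 14.9 ± 5.4 CPM (5.45, adjusted p 1.1e-06), the peptide transporter Tap1 from 5.09 ± 0.88 to 71 ± 24 CPM (3.80, adjusted p 2.2e-07) and the replication gene Mcm5 from 4.34 ± 0.69 to 16 ± 5.5 CPM (1.88, adjusted p 6.5e-05). Of 10 complement genes 8 were higher (8 over the list alone), with a median of 2.51 and a camera adjusted p of 1.2e-09 (adjusted p = 0.095 with an estimated correlation). Of 19 cytokine and chemokine genes 16 were higher and 0 lower (18 and 1 over the list alone, 10 to 19 called over the alternatives), with a median of 4.24 and a camera adjusted p of 2.9e-09 (adjusted p = 0.24 with an estimated correlation). Antigen presentation had 10 of 14 higher (10 over the list alone), a median of 1.56 and a camera adjusted p of 1.6e-06 (adjusted p = 0.26 with an estimated correlation). The class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were not called. All 16 proliferation genes were higher (16 over the list alone), with a median of 2.2 and a camera adjusted p of 2.1e-05 (adjusted p = 0.43 with an estimated correlation).

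Interferon genes rose in each library labelled cKO at 4 weeks, to very different levels. Ifi27l2a, a small interferon-induced protein, rose from 3.34 ± 0.89 to 36.9 ± 23 CPM (log2 fold change 3.46 ± 0.48, adjusted p 1.3e-04), and Oas1a, a sensor of double-stranded RNA, from 1.31 ± 0.23 to 21.9 ± 16 CPM (4.07 ± 0.58, adjusted p 1.6e-04). Ifit3, chosen after its values were seen, held 26.1, 318 and 158 CPM in the 3 libraries labelled cKO. All 27 interferon genes were higher (27 over the list alone), with a median of 3.41 and a camera adjusted p of 4e-09 (adjusted p = 0.43 with an estimated correlation). With limma-voom, the lowest of the alternatives, 16 of the 27 were called.

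The reactive and the general astrocyte list moved in opposite directions at 4 weeks, and cKO library 1 moved least in both. Its mean log2 CPM of reactive genes was 4.002, against 5.152 and 4.803 in cKO libraries 2 and 3. For general astrocyte genes it was 7.884 against 7.111 and 7.337. Cd109, a membrane protein of reactive astrocytes, rose from 5.01 ± 0.63 to 32.3 ± 3.2 CPM (log2 fold change 2.69 ± 0.15, adjusted p 7.1e-08), and Cd14, a co-receptor of bacterial lipids, from 4.54 ± 0.46 to 27.5 ± 11 CPM (2.60 ± 0.26, adjusted p 9.3e-06). Of 23 reactive astrocyte genes 18 were higher (19 over the list alone), with a median of 1.65 and a camera adjusted p of 4.2e-11 (adjusted p = 0.24 with an estimated correlation). Gfap, Lcn2, Steap4, Cp and B3gnt5 were not called. In whole cord the rise of this list, at either time, cannot be assigned to astrocytes, since microglial and interferon lists rose in the same libraries. Fgfr3, a growth factor receptor of astrocytes, fell from 216 ± 13 to 94.1 ± 28 CPM (-1.2 ± 0.15, adjusted p 7e-05), and the gap junction gene Gja1 from 320 ± 38 to 123 ± 44 CPM (-1.38 ± 0.18, adjusted p 9.1e-05). Of 15 general astrocyte genes 13 were lower and 1, Aldh1l1, higher (same over the list alone), with a median of -1.09 and a camera adjusted p of 6.1e-09 (adjusted p = 0.24 with an estimated correlation).

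Neuronal genes moved little at 4 weeks. Of 20 neuron and synapse genes 7 were lower and 0 higher (7 over the list alone), with a median of -0.291 and a camera adjusted p of 0.013 (adjusted p = 0.45 with an estimated correlation), and the count ranged from 0 with a sex term to 13 without cKO library 1 of 4.5 weeks. It was 12 without cKO library 3 of 4.5 weeks, 1 without control library 3, 3 without cKO library 2 and 4 without cKO library 3 of 4 weeks. Of 12 motor neuron genes 2 were lower (0 over the list alone, 0 to 3 over the alternatives), and the list was not called (median -0.111, adjusted p 0.49). Among 14 axon injury genes 7 were higher (7 over the list alone), with a median of 0.5 and a camera adjusted p of 0.0058 (adjusted p = 0.37 with an estimated correlation). Gadd45a, of DNA damage responses, rose from 12.2 ± 1.2 to 37.5 ± 11 CPM (log2 fold change 1.62 ± 0.17, adjusted p 1.7e-05). Of 10 immediate early genes 6 were higher (6 over the list alone), with a median of 0.638 and a camera adjusted p of 0.0021 (adjusted p = 0.15 with an estimated correlation). Arc, of synaptic activity, rose from 43.1 ± 5.5 to 111 ± 13 CPM (1.37 ± 0.11, adjusted p 1.4e-06).

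Besides Gdf15, the largest rises at 4 weeks were Xist, Apoc2 and Bglap2. Xist was 7110 times as high (95% interval 2780 to 26100), which follows the sex of the animals. Its call was lost with a sex term (adjusted p 0.48) and with limma-voom (adjusted p 0.73, the highest over the alternatives, the lowest being 4.6e-13 with DESeq2). The apolipoprotein gene Apoc2 had 0 counts in the controls and 1.46 ± 0.67 CPM in the libraries labelled cKO, a rise of at least 18-fold (adjusted p 6.1e-05), though reads of Apoc2 and its neighbour Apoc4 cannot always be told apart. Bglap2, an osteocalcin gene with near-identical copies and so of uncertain identity, rose from 0.163 ± 0.097 to 47.3 ± 5.3 CPM (log2 fold change 8.17 ± 0.42, adjusted p 5e-08). Besides Ermn, the largest falls were Dao, a D-amino acid oxidase (2.19 ± 1.9 against 19.7 ± 0.58 CPM, -3.18 ± 0.44, adjusted p 1.4e-04), Apln, which encodes apelin (14.3 ± 5.1 against 78.1 ± 7.9 CPM, -2.46 ± 0.18, adjusted p 9.8e-07), and Calr4, a calreticulin-related gene (1.06 ± 0.75 against 5.31 ± 0.88 CPM, -2.33 ± 0.36, adjusted p 2.9e-04). By edgeR's test 7179 of 19278 genes (37.2%) were called at 4 weeks, 3866 higher and 3313 lower, with 1635 and 348 beyond 2-fold. Camera called 19 lists, and 5 with an estimated correlation. With a sex term 4548 genes were called, 4373 of them shared with the 7179.

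**Figure D2:**
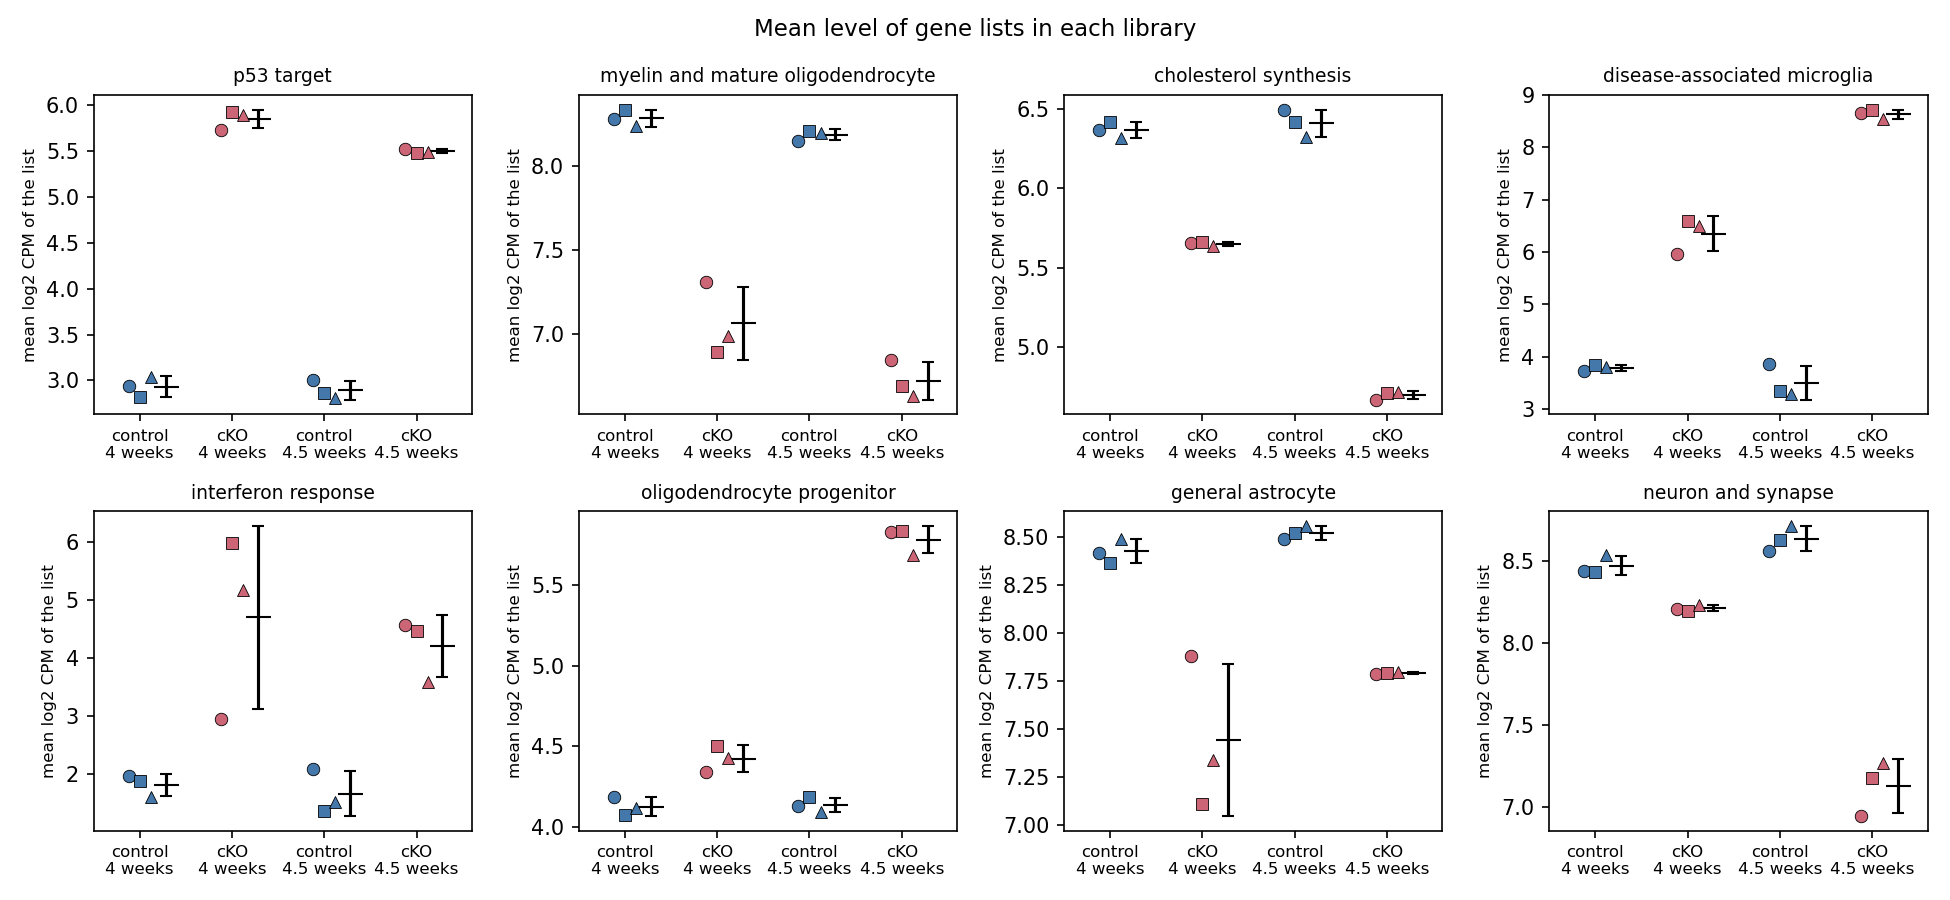
Mean log2 CPM of the members of 8 lists in each library, with bars showing the mean and SD of a group and circles, squares and triangles for replicates 1, 2 and 3. All 8 lists separate the genotypes at both times, the progenitor and neuron genes by a wider gap at 4.5 weeks.

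At 4.5 weeks transcripts of mature oligodendrocytes were lower as well. Opalin, a membrane protein of mature oligodendrocytes, held 6.2 ± 0.82 CPM in the libraries labelled cKO against 56.8 ± 1.8 CPM in controls (log2 fold change -3.20 ± 0.13, adjusted p 7.8e-10), and Gjb1, a connexin of oligodendrocytes, 19.6 ± 2.6 against 93.9 ± 0.55 CPM (-2.26 ± 0.088, adjusted p 5.2e-10). Of 28 myelin genes 26 were lower and 1, the connexin gene Gjc3 (0.43, adjusted p 0.022), higher (same over the list alone), and Cldn11 was not called. The median was -1.61 and the camera adjusted p 1.1e-15 (adjusted p = 0.18 with an estimated correlation).

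Progenitor and early oligodendrocyte genes were higher at 4.5 weeks. Matn4, the progenitor matrix protein, rose from 7.65 ± 0.23 to 135 ± 5.9 CPM (log2 fold change 4.14 ± 0.16, adjusted p 5.6e-10), and Vcan, the proteoglycan versican, from 35.8 ± 2.5 to 311 ± 27 CPM (3.12 ± 0.13, adjusted p 8e-10). Of 14 progenitor genes 13 were higher (14 over the list alone), with a median of 1.46 and a camera adjusted p of 6.7e-09. Neu4, a sialidase, rose from 14.7 ± 0.88 to 101 ± 14 CPM (2.78 ± 0.12, adjusted p 1.2e-09), and Itpr2, a calcium channel of new oligodendrocytes, from 39.8 ± 0.71 to 129 ± 15 CPM (1.69 ± 0.094, adjusted p 8.4e-09). Of 14 genes of newly formed oligodendrocytes 13 were higher (14 over the list alone), with a median of 1.68 and a camera adjusted p of 1.4e-06 (adjusted p = 0.18 with an estimated correlation).

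All sterol genes of the list were lower at 4.5 weeks. Sqle held 30.1 ± 0.51 CPM in the libraries labelled cKO against 132 ± 9.2 CPM (log2 fold change -2.13 ± 0.057, adjusted p 4.5e-11). The 21 genes had a median of -1.78 and a camera adjusted p of 6.1e-32 (21 lower over the list alone).

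The p53 targets stayed high at 4.5 weeks. Gtse1 held 26 ± 1.8 CPM in the libraries labelled cKO against 1.2 ± 0.16 CPM (log2 fold change 4.43 ± 0.14, adjusted p 1.1e-10), and Ccng1, a cyclin induced by p53, 456 ± 25 against 56.8 ± 3 CPM (3.0 ± 0.1, adjusted p 2e-10). Of 25 targets 24 were higher and 1, Zmat3, lower (-0.27, adjusted p 0.0027), the same as over the list alone, with a median of 2.44 and a camera adjusted p of 2.3e-23. Gdf15 rose from 0.13 ± 0.088 to 47.1 ± 5.9 CPM (8.46 ± 0.37, adjusted p 1.3e-09), and Sesn2 from 22.5 ± 0.67 to 59.6 ± 3.7 CPM (1.40 ± 0.075, adjusted p 5.7e-09). The integrated stress response was again divided, with 10 of 20 higher and 4 lower (same over the list alone), a median of 0.462 and a camera adjusted p of 0.033 (adjusted p = 0.15 with an estimated correlation). The lower genes were Asns (-1.11), Slc7a11 (-1.13), Phgdh (-0.44) and Vldlr (-0.24), which serve amino acid and lipid supply.

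Bax rose from 20.5 ± 1.3 to 63.4 ± 2 CPM at 4.5 weeks (log2 fold change 1.63 ± 0.066, adjusted p 7.3e-10), and Ripk1, a kinase of TNF signalling and necroptosis, from 8.6 ± 1.1 to 38.5 ± 2.7 CPM (2.16 ± 0.1, adjusted p 2.5e-09). Of 25 cell death genes 22 were higher and 1, Gsdme, lower (same over the list alone), with a median of 2.38 and a camera adjusted p of 2.7e-10 (adjusted p = 0.18 with an estimated correlation). Coil, the scaffold of Cajal bodies, fell from 20.8 ± 0.58 to 12.6 ± 0.61 CPM (-0.72 ± 0.074, adjusted p 2e-06), while Snrpb, a core protein of splicing particles, rose from 44.2 ± 1.2 to 74.6 ± 3.6 CPM (0.75 ± 0.081, adjusted p 3.2e-06). Of 26 SMN complex and spliceosomal genes 10 were higher and 7 lower (same over the list alone), and the list was not called (median 0.0845, adjusted p 0.77). Ribosomal protein genes were higher in 77 of 80 and lower in 1, Rpl3l (same over the list alone), with a median of 1.01 and a camera adjusted p of 6.1e-32 (adjusted p = 0.18 with an estimated correlation). Rpl10, of the large subunit, rose from 195 ± 9.8 to 544 ± 16 CPM (1.48 ± 0.058, adjusted p 5.7e-10).

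Microglial transcripts reached their highest levels at 4.5 weeks. Gpnmb, a glycoprotein of lipid-laden phagocytes, rose from 3.69 ± 0.26 to 2410 ± 78 CPM (log2 fold change 9.35 ± 0.18, adjusted p 1.2e-11), and Trem2 from 9.46 ± 0.33 to 396 ± 3 CPM (5.39 ± 0.12, adjusted p 1.6e-11). All 24 disease-associated microglia genes were higher (24 over the list alone), with a median of 5.36 and a camera adjusted p of 5.3e-42. Apoe, which carries lipids and was chosen after its values were seen, rose from 1732 ± 88.7 to 22430 ± 4430 CPM (3.70, adjusted p 4.6e-10). Gpr34, a lysophospholipid receptor of microglia, rose from 9.82 ± 0.85 to 110 ± 5.7 CPM (3.48 ± 0.083, adjusted p 2.5e-11). Of 13 homeostatic microglia genes 11 were higher and 0 lower (11 and 1 over the list alone), with a median of 2.42 and a camera adjusted p of 6.7e-15.

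Complement and cytokine genes were higher too at 4.5 weeks. C3ar1 rose from 1.69 ± 0.12 to 207 ± 4.3 CPM (log2 fold change 6.93, adjusted p 2.2e-10), and Tgfb1, a growth factor, from 6.83 ± 0.54 to 98.1 ± 4.7 CPM (3.85, adjusted p 3.6e-09). Of 10 complement genes 9 were higher (9 over the list alone), with a median of 4.81 and a camera adjusted p of 7.2e-08 (adjusted p = 0.14 with an estimated correlation). Of 19 cytokine and chemokine genes 16 were higher and 1, the neuronal chemokine Cx3cl1 (-1.33), lower (17 and 1 over the list alone), with a median of 4.82 and a camera adjusted p of 5.4e-04 (adjusted p = 0.48 with an estimated correlation). Antigen presentation had 12 of 14 higher (12 over the list alone), a median of 2.51 and a camera adjusted p of 5.4e-04 (adjusted p = 0.42 with an estimated correlation). The class I gene H2-D1 rose from 98.9 ± 9.1 to 781 ± 54 CPM (2.98, adjusted p 1.2e-07). All 16 proliferation genes were higher (16 over the list alone), among them the mitotic kinase Cdk1 (0.939 ± 0.15 to 11.6 ± 3.2 CPM, 3.63, adjusted p 3.6e-06), with a median of 3.37 and a camera adjusted p of 0.0015 (adjusted p = 0.62 with an estimated correlation).

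Interferon genes were higher in 26 of 27 at 4.5 weeks (27 over the list alone), with a median of 2.56 and a camera adjusted p of 0.0089 (adjusted p = 0.8 with an estimated correlation). Oas1a rose from 0.944 ± 0.43 to 18.2 ± 5.6 CPM (log2 fold change 4.27 ± 0.59, adjusted p 3.2e-05), and Bst2, an antiviral membrane protein, from 3.57 ± 1.2 to 47.4 ± 6.7 CPM (3.73 ± 0.52, adjusted p 3.4e-05). Stat2 was not called (0.85, adjusted p 0.052). With limma-voom 12 of the 27 were called, and 14 without control libraries 1 and 2 of 4.5 weeks.

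All 23 reactive astrocyte genes were higher at 4.5 weeks (23 over the list alone), with a median of 2.52 and a camera adjusted p of 4e-07 (adjusted p = 0.32 with an estimated correlation). Serpina3n, a secreted protease inhibitor, rose from 63 ± 3 to 1860 ± 200 CPM (log2 fold change 4.88 ± 0.26, adjusted p 6.2e-09), and Cd109 from 5.67 ± 1.3 to 93.3 ± 6.7 CPM (4.04 ± 0.15, adjusted p 3.4e-10). Of 15 general astrocyte genes 12 were lower and 1, Aldh1l1, higher (same over the list alone), with a median of -0.999 and a camera adjusted p of 0.035 (adjusted p = 0.74 with an estimated correlation). Mlc1, a membrane protein of astrocyte endfeet, fell from 214 ± 7.6 to 105 ± 6.3 CPM (-1.03 ± 0.1, adjusted p 1.9e-06). The folate enzyme Aldh1l1 rose from 73.8 ± 6 to 118 ± 4.8 CPM (0.67 ± 0.061, adjusted p 5.9e-07), short of the test against 1.5-fold (adjusted p 0.074, the highest over all alternatives, the lowest being 1.9e-22).

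Neuronal genes were lower at 4.5 weeks. Nefm, the middle neurofilament chain, fell from 3400 ± 170 to 686 ± 97 CPM (log2 fold change -2.31 ± 0.11, adjusted p 3.2e-09), and Thy1, a surface protein of neurons, from 608 ± 43 to 237 ± 14 CPM (-1.36 ± 0.065, adjusted p 2.3e-09). Of 20 neuron and synapse genes 19 were lower and 1, the noncoding RNA Snhg11, higher (same over the list alone), with a median of -1.47 and a camera adjusted p of 4.9e-14. Chodl, of fast motor neurons, fell from 44 ± 3.4 to 6.95 ± 1.5 CPM (-2.66 ± 0.16, adjusted p 1.5e-08). All 12 motor neuron genes were lower (12 over the list alone), with a median of -1.88 and a camera adjusted p of 7.1e-06 (adjusted p = 0.16 with an estimated correlation). Klf6, an injury-induced transcription factor, rose from 28.6 ± 2.1 to 89.2 ± 6.2 CPM (1.64 ± 0.086, adjusted p 5.1e-09), with 10 of 14 axon injury genes higher (10 over the list alone), a median of 0.985 and a camera adjusted p of 0.012 (adjusted p = 0.42 with an estimated correlation).

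The largest rises at 4.5 weeks were Apoc4, Mcoln3, Apoc2 and Olfr111. The apolipoprotein gene Apoc4 had 0 counts in the controls and 28.8 ± 6.4 CPM in the libraries labelled cKO, at least 392-fold (adjusted p 1.8e-08), and its neighbour Apoc2, with reads not always separable, was 900 times as high (95% interval 351 to 3300, adjusted p 5.5e-08). Mcoln3, a lysosomal cation channel, was 1170 times as high (95% interval 210 to 46400, adjusted p 8.9e-08), and Olfr111, an olfactory receptor gene, 1050 times (95% interval 189 to 41700, adjusted p 1.8e-08). Among the largest falls, Smyd1, a muscle methyltransferase, fell from 18.1 ± 1.8 to 0.922 ± 0.21 CPM (log2 fold change -4.30 ± 0.37, adjusted p 4.3e-07), and Hbb-bt, a haemoglobin gene hard to tell from Hbb-bs, from 4.18 ± 0.49 to 0.221 ± 0.19 CPM (-4.22 ± 0.77, adjusted p 3.3e-04). The muscle myosin Myh2 (-8.70, adjusted p 0.0065) and myoglobin, Mb (-4.80, adjusted p 0.0073), were lost without control library 2 of that time (-4.00 and -2.04, adjusted p 0.09 and 0.1), the library with muscle transcripts. Over the alternatives their adjusted p ranged from 3.5e-04 to 0.3 and from 4.8e-04 to 0.13. By edgeR's test 12701 genes (65.9%) were called at 4.5 weeks, 6418 higher and 6283 lower, with 3209 and 2189 beyond 2-fold. Camera called 21 lists, and 6 with an estimated correlation. Against a 1.5-fold change 6359 genes were called at 4.5 weeks and 1685 at 4 weeks.

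**Figure D3:**
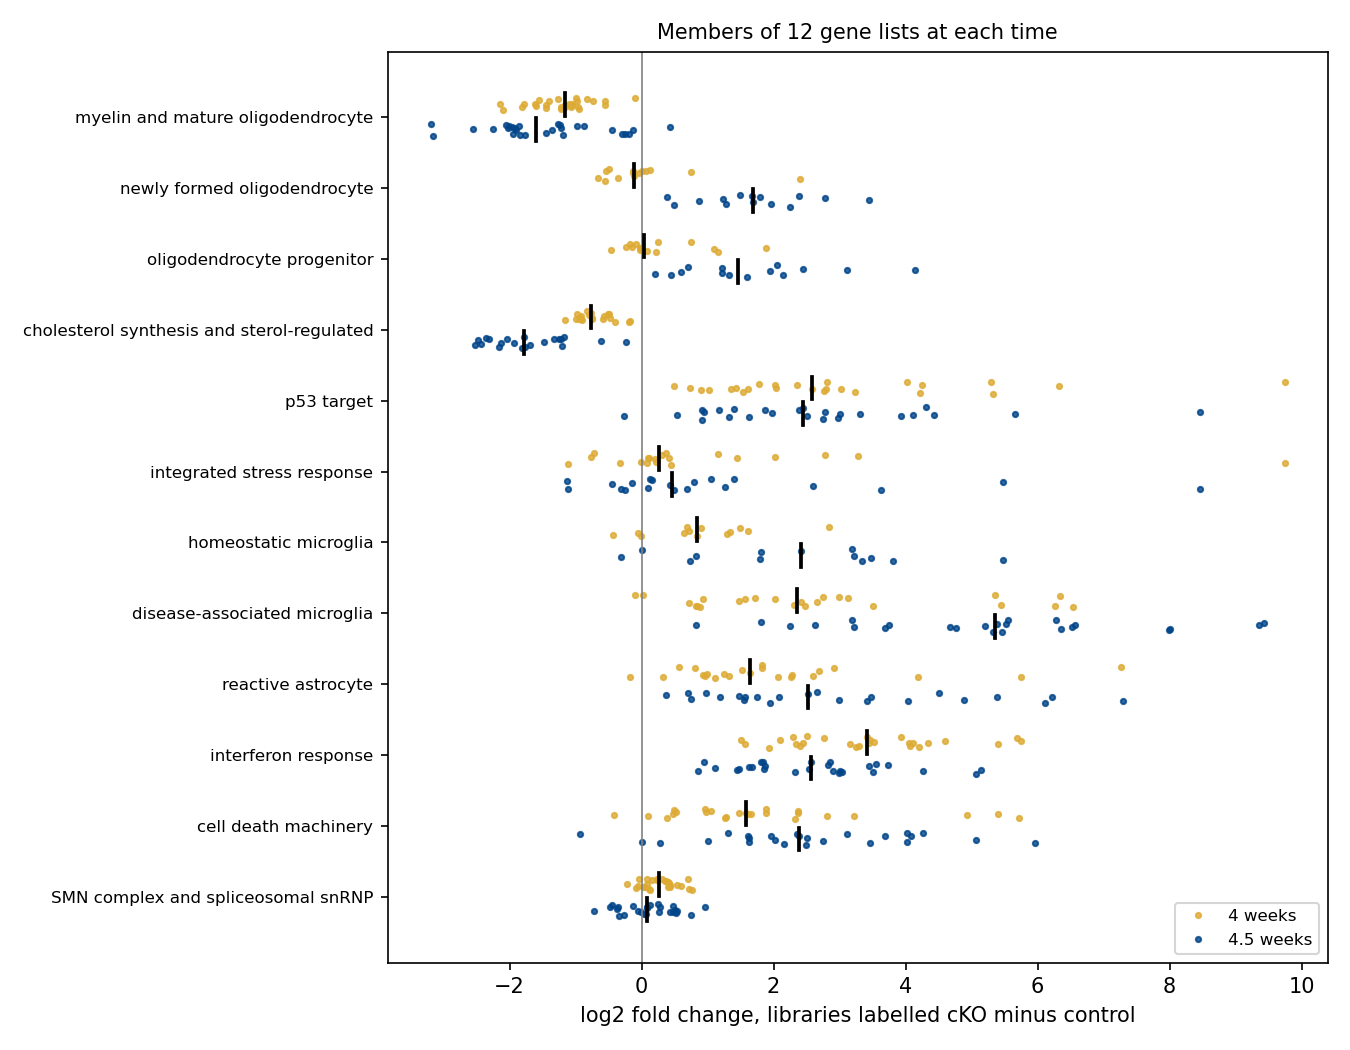
Log2 fold change, cKO minus control, of each tested member of the 12 core lists at 4 and 4.5 weeks, with black bars at the medians. The medians of progenitor and newly formed oligodendrocyte genes sit near 0 at 4 weeks and above it at 4.5 weeks.

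The genotype effect differed between the times in microglial, lineage, sterol and neuronal genes. Sex does not cancel in this difference, since control and cKO animals differed in sex at 4 weeks but not at 4.5 weeks. A part of the difference may therefore follow sex. Gpnmb rose at 4 weeks as well, from 2.91 ± 0.77 to 16.2 ± 2.46 CPM (log2 fold change 2.47), and its effect was 6.88 ± 0.23 larger at 4.5 weeks (adjusted p 1.1e-08). Ms4a4a, a membrane gene of myeloid cells, had an effect 7.74 ± 0.61 larger (adjusted p 1.4e-06), and Gp1bb, a platelet glycoprotein gene, 6.91 ± 0.48 larger (adjusted p 5.5e-07). Apoc4 differed by 10.49 (adjusted p 0.0034), a value that rests on few counts and was lost without control library 1 of 4 weeks (adjusted p 1, range over the alternatives 5.6e-10 to 1). Effects on Xist (-11.97, adjusted p 0.0028), Myh2 (-9.62, adjusted p 0.025), Myh1 (-7.85, adjusted p 0.016) and Mb (-6.17, adjusted p 0.016), of sex and muscle, differed most in the other direction. The 3 muscle genes were lost without control library 2 of 4.5 weeks (-4.88, -5.35 and -3.40, adjusted p 0.13, 0.062 and 0.069), and Myh2 and Myh1 also without cKO library 3 of 4 weeks (-7.11 and -3.78, adjusted p 0.23 and 0.27). Myh2 was lost as well without control library 1 or 3 of 4 weeks (adjusted p 0.052 and 0.055) and without cKO library 1, 2 or 3 of 4.5 weeks (0.062, 0.059 and 0.056). Over the alternatives the ranges were 0.0032 to 0.36, 0.0015 to 0.31 and 0.0015 to 0.12, and for Xist 1.5e-10 to 0.79.

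Among lists, the effect was larger at 4.5 weeks in 22 of 24 disease-associated microglia genes (median difference 2.66, camera adjusted p 6.6e-34), in 12 of 14 progenitor genes (1.27, adjusted p 6.4e-12) and in 11 of 13 homeostatic microglia genes with 1 smaller (1.58, adjusted p 2e-13). It was more negative in 20 of 21 cholesterol genes (-0.869, adjusted p 1.4e-19) and in 19 of 20 neuron genes (-1.28, adjusted p 5.4e-17). These 5 lists kept their call with an estimated correlation, at an adjusted p of 0.031 each. Newly formed oligodendrocyte genes had a larger effect in 11 of 14 (median 1.76, adjusted p 1.3e-12; adjusted p = 0.074 with an estimated correlation), and motor neuron genes a more negative one in 11 of 12 (-1.66, adjusted p 2.9e-08; adjusted p = 0.082 with an estimated correlation). Ribosomal protein genes differed in 71 of 80 (0.52, camera adjusted p 4.3e-17, and 0.58 with an estimated correlation). Their mean log2 CPM was 7.671 at 4 weeks and 7.798 at 4.5 weeks in the libraries labelled cKO. In the controls it was 7.218 and 6.863, so much of the difference came from the control groups. The myelin (median -0.317, adjusted p 0.12), interferon (-0.672, adjusted p 0.6) and SMN complex (-0.164, adjusted p 0.24) lists were not called. By edgeR's test 7841 genes differed (40.7%), 3613 upward and 4228 downward, with 1400 and 1114 beyond 2-fold. Of these, 2582 were called at 4 weeks and larger at 4.5 weeks, 1021 were called at 4 weeks and smaller or reversed, and 4238 were not called at 4 weeks.

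**Figure D4:**
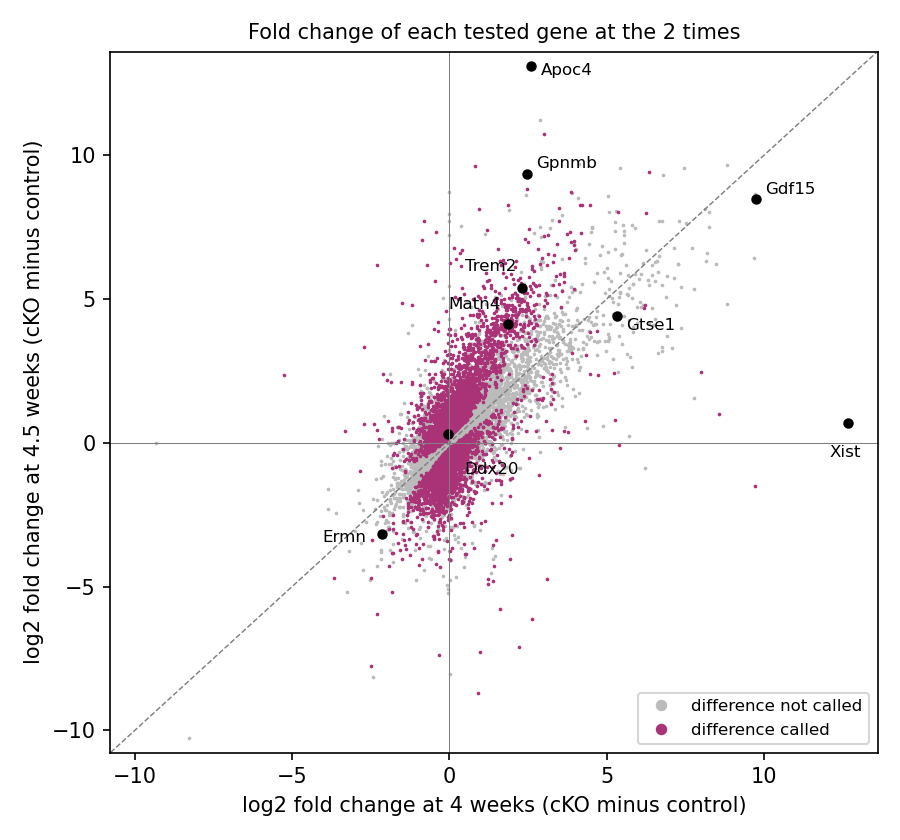
Log2 fold change, cKO minus control, at 4 weeks (horizontal) and 4.5 weeks (vertical) of all 19278 tested genes, coloured where the difference was called, with a dashed line of equality. Gpnmb and Trem2 lie above the line and Gtse1 below it, each with a called difference. Labelled genes are drawn in black whether or not their difference was called.

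Both times shared much of the response, measured against separate controls. Of the genes called higher at 4 weeks 3115 were higher at 4.5 weeks (1287 if independent), and 2535 were lower at both (1080 if independent), while 150 went from higher to lower and 224 from lower to higher. Log2 fold changes correlated across genes (Pearson r 0.702, Spearman rho 0.645). For the mean of the 2 effects 12628 genes were called, 6422 higher and 6206 lower. All 25 p53 targets (median 2.61) and all 24 disease-associated microglia genes (3.88) were higher on this mean, and all 28 myelin (-1.44) and all 21 cholesterol genes (-1.34) were lower.

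The control groups differed in sex as well as time. Ddx3y and Eif2s3y, Y-linked genes of translation, had 0 counts at 4.5 weeks and were at least 657-fold and 322-fold lower there (adjusted p 0.026 and 0.035), Xist was 11500 times as high (95% interval 4470 to 42100, adjusted p 0.0029), and Fam220a, a gene of little-known function, 495 times (95% interval 137 to 4090, adjusted p 0.0072). With a sex term none of Ddx3y (adjusted p 0.42, range over the alternatives 1.6e-05 to 0.72), Eif2s3y (0.49, range 1.3e-04 to 0.88), Fam220a (1, range 1.5e-04 to 1) and Xist (0.73, range 1e-12 to 0.73) was called. By edgeR's test 3227 genes were called, 1837 higher and 1390 lower at 4.5 weeks (16.7%). With upper quartile scaling the split was 1524 higher and 1809 lower. Ribosomal protein genes were lower in 71 of 80 (median -0.379, camera adjusted p 7.6e-53; adjusted p = 0.72 with an estimated correlation) and blood genes in 4 of 5 (-1.96, adjusted p 0.0069; adjusted p = 0.9 with an estimated correlation).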

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

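Of the tests in this part, the list medians compared between astrocytes and neurons, the order of libraries on p53 targets, the interval of Ddx20, the sex term, the count of male libraries and the comparison of control groups were chosen only after the result was seen.

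The genotype effect at 4.5 weeks differed from that at 4 weeks, by edgeR's test of the difference at an adjusted p below 0.05, in 62 of 94 named genes, 29 upward and 33 downward, and by camera in 12 lists, of which 5 (disease-associated and homeostatic microglia, progenitor, cholesterol and neuron) kept the call with an estimated correlation. Some of the 94 genes were named because they differed most between the times, so their count is partly fixed by the choice. Over all tested genes 7841 of 19278 (40.7%) differed. Control and cKO animals differed in sex at 4 weeks only, so a part of any difference may follow sex. Each value below is the effect at 4.5 weeks minus the effect at 4 weeks in log2 units.

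In the oligodendrocyte lineage the difference was -1.01 for Ermn, -0.45 for Aspa, -1.29 for Gjb1 and -2.14 for Opalin, of mature cells. Camera did not call the myelin list as a whole for this difference. The difference was 1.03 for Enpp6, 2.81 for Neu4 and 1.8 for Itpr2, of newly formed cells. For the progenitor genes Matn4, Cspg4 and Vcan it was 2.26, 1.29 and 2.36. The newly formed oligodendrocyte list had a median difference of 1.76 (adjusted p = 0.074 with an estimated correlation) and the progenitor list 1.27. Sterol enzymes differed by -1.16 (Hmgcs1) and -1.22 (Sqle), and the cholesterol list by -0.87.

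Microglial, myeloid and complement genes differed upward: Fcrls 2.63, Gpr34 2.59, Trem2 3.08, Ctsd 2.66, Gpnmb 6.88, Ms4a4a 7.74, C3ar1 3.52 and C1qc 2.88. The cytokine genes Tgfb1 and Csf1 differed by 2.31 and 0.92, though camera did not call the cytokine list for this difference. The disease-associated microglia list differed by 2.66, the homeostatic list by 1.58 and complement by 1.88 (adjusted p = 0.28 with an estimated correlation). The border macrophage genes Ms4a7 and Pf4 differed by 5.79 and 2.5, and the class I gene H2-D1 by 1.64. Among reactive astrocyte genes Cd109 differed by 1.35, Cd14 by 1.92 and Serpina3n by 2.61, and the list by 0.59 (adjusted p = 0.82 with an estimated correlation). The general astrocyte genes Fgfr3 and Aldh1l1 differed by 0.83 and 0.41.

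Among p53 targets the difference was -0.90 for Gtse1, -0.98 for Eda2r and -0.62 for Sesn2, while camera did not call the p53 list as a whole. The necroptosis kinase Ripk1 differed by 1.21, and the cell death list by 0.62 (adjusted p = 0.82 with an estimated correlation). In the splicing list Snrpa1 differed by -0.63 and Coil by -0.64. Ribosomal protein genes differed by 0.34 (Rps19) and 1.01 (Rpl10), and their list by 0.52 (adjusted p = 0.58 with an estimated correlation). Chaperone genes differed by -1.04 (Hsp90aa1), -1.05 (Hsph1) and -0.64 (Dnajb1), and the heat shock list by -0.50 (adjusted p = 0.58 with an estimated correlation).

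Neuronal genes differed downward: Rbfox3 -0.97, Slc32a1 -1.61, Thy1 -1.28, Nefm -2.08, Chodl -2.16 and Ache -1.50. The neuron list differed by -1.28 and the motor neuron list by -1.66 (adjusted p = 0.082 with an estimated correlation). Further differences were -0.93 for Apln, -0.87 for the ependymal gene Foxj1, 6.91 for Gp1bb and -2.37 for Smyd1. Apoc4 differed by 10.49, not an exact size as its controls at 4.5 weeks had 0 counts, and was not called without control library 1 of 4 weeks (adjusted p 1). Genes of sex and of blood, and genes listed for neighbouring tissues, differed too. These were Xist -11.97, Myh2 -9.62, Myh1 -7.85, Mb -6.17, Acta1 -5.70, Hbb-bt -3.79, Hba-a2 -3.04, Trpv1 -4.46, Avil -5.50 and P2rx3 -1.78. Some of these rest on single control libraries of 4.5 weeks. Avil held 36.1 CPM in control library 1 of that time against 0.259 and 0.627 CPM in the other 2, and Trpv1 3.46 against 0 and 0.112 CPM. The effect on P2rx3 at 4.5 weeks went from -1.65 to -0.70 without that library. That on Acta1 went from -4.29 to -1.44 (adjusted p 0.25) without control library 2, without which the differences of Myh2, Myh1 and Mb were not called either. Hba-a2 cannot be told from Hba-a1 with certainty, as their sequences are near-identical.

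Ddx20 was not lower in the libraries labelled cKO. An exchange of single libraries between control and cKO needs libraries out of place in both groups, and 0 libraries overlapped the other genotype of their time on the mean of p53 targets. An exchange of whole groups is not excluded by that count. Transcript kept after deletion of part of the gene may leave the gene-level count in place, and so may deletion in too small a share of the cells of the cord. The interval at 4 weeks, whose lower end was -0.254, cannot settle this, since counts per gene do not show exons.

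Ribosomal protein genes were higher in the libraries labelled cKO, and their transcripts are short (median 712 bases against 2231 for all genes). Transcript length bias was argued against at both times: the list's medians of 0.439 and 1.01, over 77 members with a length, stood at percentile 100 of 10000 random lists matched on length and expression, whose medians were -0.0343 (-0.0951 to 0.0418) and -0.334 (-0.505 to -0.121). Sex of the animals was argued against as the whole cause, as the median at 4 weeks was 0.486 with a sex term and 0 of the libraries at 4.5 weeks were male. The median also differed by -0.379 between the control groups, so a difference between library batches at 4 weeks, when no batch is given, cannot be told apart from genotype and may contribute. A biological cause stays open and was not tested.

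Astrocyte and neuron markers fell in the libraries labelled cKO, where microglial RNA rose. Dilution by RNA of other cell types would lower both alike. The astrocyte median minus the neuron median was -0.801 at 4 weeks (permutation p 4e-05, shuffled range -0.435 to 0.357). At 4.5 weeks it was 0.474 (permutation p 0.013, shuffled range -0.326 to 0.307), over 100000 resamples. The shuffling treats genes as independent, so these p do not measure the spread between animals. Astrocyte list levels (mean log2 CPM) went from 8.427 to 7.444 at 4 weeks and from 8.524 to 7.791 at 4.5 weeks (SD at most 0.397). Neuron list levels went from 8.472 to 8.214 and from 8.638 to 7.128 (SD at most 0.166). These levels argue against dilution alone, while a part of each fall may still come from it. Transcript length bias as the whole cause was argued against by matched lists. The neuron list at 4.5 weeks (median -1.47) stood at percentile 0 (random medians -0.485, -0.86 to -0.0247). For the astrocyte list at 4 weeks the percentile was 0 too (-0.148, -0.306 to 0.0194). The lists matched to neuron genes fell as well, so a part of the neuronal fall may follow length or expression. Loss of cells and lower transcription per cell stay open and were not tested.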

How the results depend on the processing

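The sex term, the fit without control libraries 1 and 2 of 4.5 weeks and the removal of a trend with transcript length were chosen only after the data were seen. The analysis of minor-intron genes and its alternative splice site were not run, because a genome sequence was not used here, and contrasts between times cannot be fitted for each time alone. Under the other alternatives run, counts of called genes stayed within 1.5 times the reported ones except as follows, and the cause was not tested unless named. The test against a 1.5-fold change, stricter by construction, called 1685 genes at 4 weeks, 6359 at 4.5 weeks, 2309 for the difference, 4248 for the mean and 1 between the control groups, and Ddx20 at 4.5 weeks (0.325) had an adjusted p of 1. With a sex term 4548 genes were called at 4 weeks and 0 between the control groups (1999 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 45), where sex and time coincide. With control libraries 1 and 2 of 4.5 weeks left out, 390 genes differed between the control groups, with fewer libraries, and Ddx20 at 4.5 weeks (0.331) had an adjusted p of 0.099. With the transcript length trend removed, 1904 genes differed between the control groups, Ddx20 at 4 weeks reversed to 0.0154, never called, and its difference between times was called (0.391, adjusted p 0.038), as it was with a minimum of 1 CPM in 3 libraries (0.363, adjusted p 0.049, fewer genes tested). Over the alternatives the adjusted p of that difference ranged from 0.038 to 1.

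With each library left out in turn, calls numbered 5476 to 7760 at 4 weeks, 11754 to 13033 at 4.5 weeks, 6979 to 7760 for the difference and 12161 to 12857 for the mean. Between the control groups they numbered 1313 (without control library 1 of 4 weeks) to 3773, with 1476 without control library 2 of 4 weeks, and 1528 and 2070 without control libraries 2 and 3 of 4.5 weeks. Ddx20 ranged from -0.0882 to 0.00138 at 4 weeks (reversed without cKO library 3), from 0.261 to 0.389 at 4.5 weeks (not called without cKO library 3 or control library 1 of that time), from 0.294 to 0.422 for the difference (called at 0.422, without cKO library 2 of 4.5 weeks, adjusted p 0.046) and from -0.17 to -0.065 between the control groups. Numbers do not pair the libraries: 1 of 6 correlated best with the control of its own number, and a replicate block gave 6339, 12167, 7144, 12062 and 2799 calls. Lists called by camera fell from 19 to 5 at 4 weeks, from 21 to 6 at 4.5 weeks, from 12 to 5 for the difference and from 2 to 0 between the control groups with an estimated correlation; fry called 23, 28, 18 and 1. None of 161 effects of genes chosen by the rule, Ddx20 aside, reversed, and calls were lost in 35 with the test against a 1.5-fold change, 17 with a sex term, 14 with limma-voom, 13 without control libraries 1 and 2 of 4.5 weeks, 9 with a robust spread, 6 each with DESeq2 and a replicate block, 2 with the length trend removed, 1 with each time fitted alone and 2 to 9 with a library left out. In the self-test, with far fewer genes changed than were called in the data, 6% and 8.16% of 1.25-fold changes were found at 4 and 4.5 weeks.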

Other observations

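The tests reported in this part were planned, while the sex term and 2 other alternatives chosen only after the data were seen enter the ranges, and genes outside the rule were chosen after their values were seen. Ranges of called members cover the alternatives other than the test against a 1.5-fold change, which calls fewer by construction (vesicle transport 0 at 4 weeks; endothelial 0 at 4 and 2 at 4.5 weeks; pericyte and smooth muscle 1 and Schwann cell 3 at 4.5 weeks). Where edgeR called 0 members of a list at 4 weeks, 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0, except 1 unadjusted in the T and natural killer cell list and 1 in the mitochondrial list, and 1 blood gene called by limma-voom.

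Several lists fell outside the comparisons above. The effect on vascular lists was not called as different between the times (endothelial median difference 0.674, camera adjusted p 0.074, and pericyte and smooth muscle 0.444, adjusted p 0.19). At 4.5 weeks, of 12 endothelial genes 7 were higher and 1, Itm2a, lower (8 and 1 over the list alone, 4 to 9 called over the alternatives, 4 without control library 2 or cKO library 3 of 4.5 weeks), against 1 and 3 at 4 weeks (2 to 6 called over the alternatives). Camera called neither (median 0.372, adjusted p 0.53, and median -0.297, adjusted p 0.15). Of 10 pericyte and smooth muscle genes 6 were higher and 1 lower at 4.5 weeks (7 and 1 over the list alone, median 0.421, adjusted p 0.5, 3 to 8 over the alternatives), among them Tagln, an actin-binding protein, from 11 ± 6.4 to 51.9 ± 8.4 CPM (log2 fold change 2.24, adjusted p 3.2e-05). At 4 weeks 1 was lower (0 over the list alone, median -0.119, adjusted p 0.63). With a robust spread 0 were called there, and with each time fitted alone 3. Ependymal genes were higher in 7 of 9 at 4.5 weeks (median 0.945, adjusted p 0.23) and in 3 of 9 at 4 weeks (4 over the list alone, median 0.254, adjusted p 0.088), where the cilia regulator Foxj1 rose from 34.9 ± 2.3 to 83 ± 8 CPM (1.25, adjusted p 1.2e-07). Immediate early genes were higher in 8 of 10 at 4.5 weeks (median 1.02, adjusted p 0.054).

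Some chaperone genes were lower at 4.5 weeks. Hsp90aa1, a cytosolic chaperone, fell from 1510 ± 18 to 596 ± 30 CPM (log2 fold change -1.34, adjusted p 4.3e-09), with 5 of 9 heat shock genes lower, Hspe1 higher and 3 not called (same over the list alone), a median of -0.406 (-0.219 without control libraries 1 and 2 of 4.5 weeks) and a camera adjusted p of 0.035 (adjusted p = 0.48 with an estimated correlation). At 4 weeks 2 were higher and 2 lower (same over the list alone), and the list was not called (median -0.0122, adjusted p 0.73). These 4 calls became 2 without control library 1 or 3 or cKO library 2 or 3 of 4 weeks, and 1 with a sex term. Autophagy genes went both ways at 4.5 weeks. Lamp2, of the lysosomal membrane, rose from 132 ± 7.7 to 343 ± 11 CPM (1.38, adjusted p 9.5e-09) and Lamp1 from 623 ± 5.4 to 1240 ± 53 CPM (0.99, adjusted p 1e-08), but 11 of 19 members were lower and 4 higher (same over the list alone, median -0.279, adjusted p 0.41). At 4 weeks 6 were lower and 2 higher (same over the list alone, median -0.0678, adjusted p 0.29), and the 8 calls became 5 without cKO library 2 of 4 weeks and 3 with a sex term. Vesicle transport genes went both ways at 4.5 weeks, 11 higher and 12 lower of 27 (same over the list alone, adjusted p 0.98, median -0.0624 against a mean of 0.0172), with the sorting nexin Snx5 rising from 111 ± 2 to 345 ± 19 CPM (1.63, adjusted p 1.1e-10). At 4 weeks 2 were higher and 6 lower (1 and 6 over the list alone, median -0.0445, adjusted p 0.29, 2 to 11 called over the alternatives). Mitochondrially encoded genes had 0 of 13 called at 4 weeks (median 0.0346, adjusted p 0.87), or 1 with a replicate block. At 4.5 weeks 4 were lower, mt-Nd2, mt-Nd4, mt-Nd5 and mt-Nd4l (median -0.144, adjusted p 0.5).

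Border macrophage genes called at 4.5 weeks were all higher, while called genes of blood-borne cells were mixed. The mean log2 CPM of the border macrophage list at 4.5 weeks was 2.028, 2.048 and 2.094 in the libraries labelled cKO. In the controls of that time it was 1.373, -0.6804 and -1.039. Border macrophage genes had 0 of 8 called at 4 weeks (median -0.0904, adjusted p 0.73) and 3 higher at 4.5 weeks, F13a1, Pf4 and Ms4a7 (median 1.03, adjusted p 0.34, 3 to 7 over the alternatives, 6 without control library 1 of that time). Ms4a7 rose from 0.271 ± 0.25 to 19.4 ± 2.4 CPM (log2 fold change 6.15, adjusted p 6.6e-07). Of 10 monocyte and neutrophil genes 1 was higher at 4 weeks (median -0.562, adjusted p 0.63, 0 to 2 over the alternatives, 2 without cKO library 2 of that time) and 2 higher and 1 lower at 4.5 weeks (2 and 0 over the list alone, median 0.62, adjusted p 0.7, 2 to 5 over the alternatives, 5 under some, such as without cKO library 1 of 4 weeks). T and natural killer cell genes had 0 of 5 called at 4 weeks (median 0.637, adjusted p 0.88) and 1 higher and 2 lower at 4.5 weeks (median -0.847, adjusted p 0.77). Of 6 B cell genes 1, the immunoglobulin gene Ighm, was lower at 4 weeks (-0.69, adjusted p 0.0033, but 0.096 with a sex term, range over all alternatives 5e-05 to 0.59; list median -0.138, adjusted p 0.71), and at 4.5 weeks Ighm fell (-2.25, adjusted p 7.5e-08) and Cd79b, of the B cell receptor, rose (3.06, adjusted p 1.6e-04). There the median was 0.0826 and the mean 0.262 while camera's direction was down (adjusted p 0.77). All 5 blood genes were lower at 4.5 weeks (median -3.79, adjusted p 0.096) and 0 at 4 weeks (median -0.362, adjusted p 0.48), or 5 without cKO library 1 of that time. With single libraries left out, the medians of the T and natural killer cell, monocyte and neutrophil, and blood lists at 4 weeks and of the border macrophage list at 4.5 weeks moved by over 1.5 times, and that of the blood list turned to 0.0115 without cKO library 3 of 4 weeks.

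Lists of neighbouring tissues depended on single libraries, except the sensory ganglion list at 4 weeks. Of 11 skeletal muscle genes 9 were lower at 4.5 weeks (median -3.92, adjusted p 0.53) and 0 at 4 weeks (median 1.39, adjusted p 0.75), and the 9 became 0 without control library 2, 1 without cKO library 2 and 2 without cKO library 3 of 4.5 weeks. The median at 4.5 weeks became -0.875 without control library 2 of that time, and the median at 4 weeks turned to -0.625 without cKO library 3 of that time. Of 10 Schwann cell genes 2 were lower at 4 weeks (median -0.594, adjusted p 0.31, 0 to 6 over the alternatives), and 2 were higher and 4 lower at 4.5 weeks (2 and 2 over the list alone, median -1.77, adjusted p 0.99, 4 to 8 over the alternatives). That median turned to 0.372 without control library 1 of 4.5 weeks and to 0.849 without control libraries 1 and 2. Meningeal fibroblast genes had 0 of 11 called at 4 weeks (median -0.0214, mean 0.115, adjusted p 0.81) and 2 lower at 4.5 weeks (0 over the list alone, median 0.357, or -0.067 without control library 3 of that time, mean -0.784, adjusted p 0.99, 0 to 6 over the alternatives). Of 4 sensory ganglion genes, too few for camera, 2, Avil and Trpv1, were higher at 4 weeks (median 2.7), though DESeq2 gave neither an adjusted p, and 2 lower at 4.5 weeks (median -0.868), among them P2rx3 (-1.65). Without control library 1 of 4.5 weeks P2rx3 stood at -0.697, 4 were called and the list's median turned to 1.98. It also turned to 0.682 with limma-voom and to 0.448 with a replicate block.

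Other splits of the libraries were fitted in the same way. At 4 weeks the real split called 7179 genes and the highest of the other splits 0, at 4.5 weeks 12701 and 1, and between the control groups 3227 and 0, with 1 of 10 splits as large in each. These splits are too few for a share under 0.05. For the mean effect 1 of 100 splits, the real one, reached 12628 calls, which makes chance unlikely without excluding it. The highest other reached 9887 and kept the real groups at 4.5 weeks, so that time carries much of the count. For the difference between times these splits cannot address chance, because they regroup control and cKO libraries within each time. They therefore do not test whether the genotype effect was equal at both times. Of 100 splits, 8, the real one among them, reached 7841 calls, and the highest other reached 12628. Of the 7 others, 1 kept the real groups at both times with 1 time exchanged and 6 kept the real groups at 4.5 weeks, so this count reflects the genotype structure of the samples.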
